A study of Apis mellifera with 2 samples.

How the data were processed

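RNA was sequenced from hemocytes, the blood cells that circulate in the open body cavity of insects, of the honey bee Apis mellifera at 2 life stages, with 1 library per stage. Per the labels' protocols, the adult library came from bees under 1 day old that emerged from capped brood kept at 34 °C and were gathered every 24 h. The larval library came from worker larvae 8 days old, in the last feeding instar. Each RNA preparation started from the cell pellet of 320 µL of hemolymph, and how many insects were pooled is not given in the sources used here. Polyadenylated RNA was selected with oligo(dT) beads, and read pairs of 150 bases per end were sequenced on a DNBSEQ instrument. The library protocol marks strand with dUTP, but whether the counting used strand is not given in the sources used here, so reads of overlapping antisense genes cannot be separated.

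The authors deposited estimated counts per coding sequence, obtained with kallisto per the submitters' processing notes. Its version, index, trimming and genome build are not given in the sources used here. The authors' TPM, values relative to length and depth, stood beside the estimated counts and summed to 1000000 in each library, per the file headers and values. The targets were 23471 RefSeq coding sequences, including 13 encoded by the mitochondrial genome, and hold no untranslated regions, so lengths are coding lengths. kallisto divides a read pair that matches several sequences among them, so values of near-identical gene copies (major royal jelly proteins, odorant-binding proteins, odorant receptors) are uncertain. Of the estimated counts, 11617 in the adult and 11091 in the larval library were not whole numbers at a tolerance of 0.001.

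From these files, estimated counts were summed to genes through the protein identifiers in a RefSeq gene table of assembly Amel_HAv3.1, used only for names and for which genes neighbour each other. All 23471 coding sequences matched, giving 9935 genes, of which 398 have a symbol and 9537 a locus number only. Sums were rounded to whole numbers. The adult library held 16880784 and the larval library 17657463 estimated counts, and 3 counts, the one-sided 95% limit that a count of 0 allows, correspond to 0.158 scaled CPM in the adult and 0.192 CPM in the larval library. Library sizes were scaled with TMM (edgeR 4.0.16, R 4.3.3), with factors of 1.13 for the adult and 0.886 for the larval library. Genes with at least 10 counts over both libraries (8798 genes) were compared. The log2 fold of adult over larva was computed with a prior of 0.5 counts, and folds without logs include the same prior, so they lie below the ratio of the CPM printed beside them where counts are low. Where the lower library had 1 to 3 counts the plain ratio of scaled CPM is given, called a ratio, and intervals are those of the plain ratio. Intervals are exact 95% intervals (Clopper-Pearson on the split of a gene's counts between the libraries; exact Poisson for CPM; exact binomial for shares). The exception is the gaps by coding length, whose 95% intervals come from a bootstrap, which draws genes anew with replacement. The exact intervals cover counting error only, since each stage has 1 library. They may be too narrow even for that, since reads amplified by PCR are not independent molecules. A fold against 0 counts was computed at this floor of 3 counts and is a lower bound in that sense only: it takes the count of the higher library as exact, and the lower end of the wider central exact interval lies below it.

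With 1 library per stage there is no replicate check, no p-value and no standard error, and every value compares these 2 libraries, not the stages. A large difference was therefore a rule of size: at least 4-fold, with the interval bound nearest to 1 also at 4-fold or more, and at least 10 CPM in the higher library. A gene list was described by the percentile of its median log2 fold among 10000 random lists of the same size matched on mean expression in 20 bins. Lists with under 3 measured members have values only, and a list below percentile 2.5 or above 97.5 is said to lie apart. On simulated counts with counting error alone, 100% of 100 genes changed 8-fold, 0% of 100 genes changed 2-fold and 0% of 8602 unchanged genes met the size rule. Over the 8802 simulated genes, 95.4% of intervals held the true fold, and 8% of 100 random lists of unshifted genes lay beyond the outer percentiles. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 did the rest, and matplotlib 3.10.9 drew the plots.

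The design, size rule, list themes and rule for named genes were set before the data were examined. They covered 30 lists defined by patterns in product descriptions or symbols. The gene table used here pairs genes with symbols and not with product descriptions, so members were assigned by symbol after the gene table was seen and before any fold was computed. This gave 27 lists: antimicrobial peptides, phenoloxidase and melanization, pathogen recognition, phagocytic receptors, tetraspanins, cell adhesion, toll and Imd signalling, hemocyte markers, fat body storage proteins, muscle, cuticle, larval silk gland, royal jelly, venom gland, neurons, odorant-binding and chemosensory proteins, oenocytes, cytosolic ribosomal proteins, mitochondrially and nuclear-encoded oxidative phosphorylation, glycolysis and citric acid cycle, chaperones, antioxidant defence, ecdysone and juvenile hormone response, lysosome, odorant receptors and CYP6 enzymes. The last pair was added once the gene table was seen. Integrins, basement membrane, gut, cell cycle, proteasome and caspase genes had no member with a symbol and are not analysed here.

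The named genes are (a) the 10 with the largest fold in each direction among large differences with at least 50 CPM in the higher library, (b) the 5 most abundant genes of each library, (c) the most abundant member of each list and, among members with at least 10 CPM in the higher library, the one with the largest fold, and (d) the 3 most abundant members of each immunity, surface and hemocyte list. Part (a) was written for genes with a product description and was applied to genes with a symbol. Above the last gene named under it, 66 locus-number genes on the adult side and 138 on the larval side were passed over. The value of 1 gene under the rule is not reported here. Alternatives were plain totals, DESeq2 1.42.0 median of ratios, the authors' TPM (pseudocount 0.03), other count filters, a prior of 5 counts, totals without the other-tissue lists, the single coding sequence with most counts, other fold and CPM minimums, and other ways to match or average lists. Coordinates, sequence checks such as GC content, and proteomic measurements are not analysed here.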

Results

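The series set out to map surface molecules of honey bee hemocytes, and its sequencing part holds 2 polyadenylated RNA libraries, 1 from newly emerged adult bees and 1 from last-instar worker larvae. They held 16880784 (adult) and 17657463 (larva) estimated counts over coding sequences. At least 1 count was found for 9383 genes in the adult and 9245 genes in the larval library, 9062 of them shared. Among 8798 genes compared, 276 met the size rule of 4-fold as higher in the adult library and 239 as higher in the larval library. Across the 6773 genes with a mean of 10 CPM or more, Spearman's rho between the libraries was 0.745. With 1 library per stage the differences have no replicate check.

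The question was which genes differ between hemocytes of the newly emerged adult and of the larva. On the adult side, the leading genes with a symbol were Eth and Vg, which encodes the yolk precursor vitellogenin. Eth stood at 64.2 CPM in the adult library against 2 counts (0.128 CPM) in the larval one, a ratio of 502.5 with an interval of 139 to 4154, and Vg at 120 against 0.320 CPM, 340-fold higher (160 to 1154). Cyp4g11, a cytochrome P450 of the subfamily that makes cuticular hydrocarbons, was 48.1-fold higher (33.6 to 74.6) and Mblk-1, a transcription factor known from mushroom body neurons, 35.2-fold higher (24.8 to 53.6). PGRP-S3, a peptidoglycan recognition protein, was 20.9-fold higher (16.7 to 27.1).

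Among the other genes with a symbol that led on the adult side, Ip3k, an inositol trisphosphate kinase, reached 1358 CPM against 126 (10.8-fold), and Pkc, protein kinase C, 620 against 64.0 CPM (9.69-fold). The synaptotagmin Syt20, of a family that acts in vesicle fusion, stood at 487 against 61.2 CPM (7.95-fold). A4 was 11.0-fold higher at 134 CPM, and the cytochrome P450 gene CYP6AQ1 8.39-fold higher at 618 CPM.

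On the larval side, storage proteins of the hemolymph led among genes with a symbol, with 138 locus-number genes passed over. HEX70b was 738-fold higher in the larval library (568 to 998), at 2034 against 2.73 CPM, and Hex110 413-fold higher (359 to 482), at 4002 against 9.66 CPM. Hex70c was 64.7-fold and Hex70a 20.3-fold higher, and Vhdl, a very high density lipoprotein of the hemolymph, 131-fold higher (90.4 to 207). The adult counts came to 0.163% of the larval counts for HEX70b, 0.294% for Hex110, 1.87% for Hex70c and 5.998% for Hex70a. The ecdysone-responsive transcription factors Br-c and E74 were 325-fold (153 to 1101) and 7.50-fold (6.44 to 8.80) higher in the larval library. The mitochondrial genes ND2 and ND5, subunits of respiratory complex I, were 5.29-fold and 5.09-fold higher, and Reck, a membrane-anchored inhibitor of metalloproteinases, 4.60-fold higher at 418 against 90.9 CPM.

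The share of counts in the other library sets a limit on the widest folds. Among abundant genes, picked after their values were seen, it was lowest at 0.148% (0.0811 to 0.249) for LOC410747, a larval-side gene, and at 0.124% (0.0337 to 0.317) for LOC412818, an adult-side gene. The counts of HEX70b (0.163%) and Br-c (0.341%, 0.111 to 0.798) in the adult library, and of Eth (0.163%, 0.0198 to 0.592) and Vg (0.219%, 0.0711 to 0.513) in the larval library, did not exceed these shares beyond counting error. The same held for Pgrp-s2 and Obp3, which had 1 and 2 larval counts. Any carry-over would add to the counts of the lower library and make these folds too small. The lowest shares come from these same libraries, and the rate of carry-over was not measured.

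**Figure D1:**
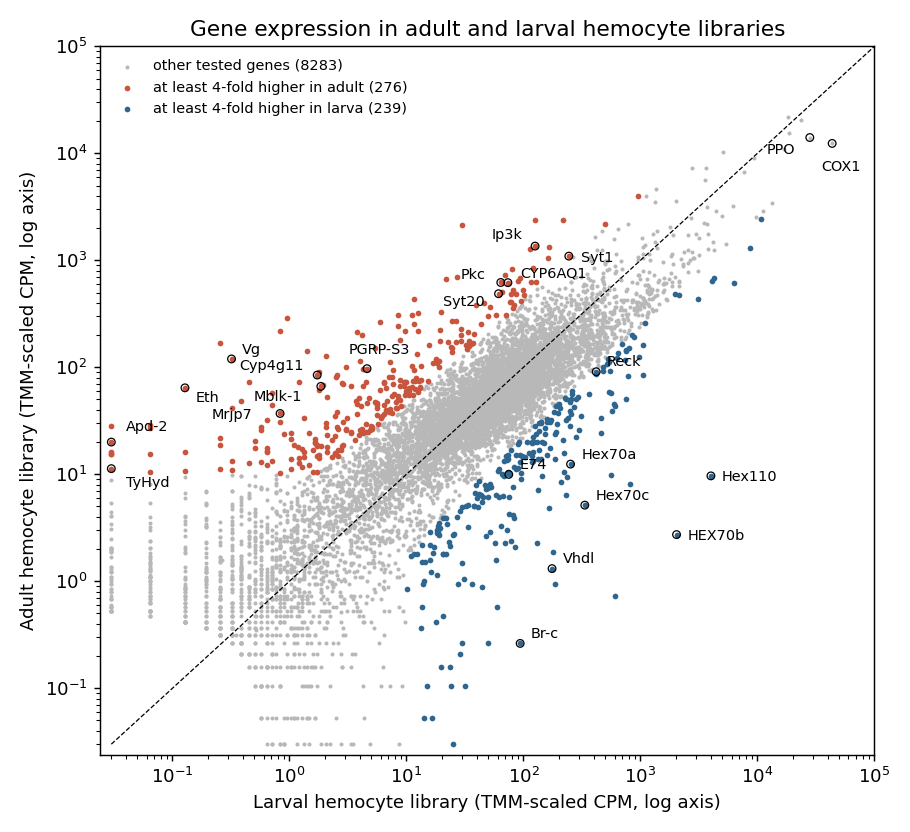
Scaled CPM of each compared gene in the larval library (horizontal, log axis) and in the adult library (vertical, log axis), with genes at 0 counts drawn at the edge, named genes ringed and a dashed line of equal values. The 276 genes in red met the 4-fold size rule as higher in the adult library and the 239 in blue as higher in the larval one, and HEX70b (2034 against 2.73 CPM) and Hex110 (4002 against 9.66 CPM) are the ringed genes farthest to the lower right.

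By CPM, which is not corrected for coding length, the same 5 genes were the most abundant in both libraries. PPO, the prophenoloxidase that hemocytes make for melanization, stood at 14041 CPM in the adult and 28019 CPM in the larval library, a log2 fold of -0.997. COX1, the mitochondrial cytochrome c oxidase subunit, stood at 12373 and 43506 CPM (log2 fold -1.81). LOC411597 reached 21934 CPM in the adult and 18195 CPM in the larval library, a log2 fold of 0.27. The neighbouring genes LOC408551 and LOC408552 had log2 folds of -0.21 and -0.26, and both were higher in the adult library under plain totals and under the authors' TPM. The 10 most abundant genes held 14.6% of adult counts (exact binomial interval 14.589 to 14.622) and 17.2% of larval counts (17.166 to 17.201).

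Among immunity genes, pathogen recognition was the list on the adult side. Its 4 members had a median log2 fold of 3.03, at percentile 99.99 of matched random lists, and 3 were higher in the adult library. Besides PGRP-S3, these were Pgrp-s2, with 295 adult counts against 1 larval count (ratio 242, interval 43.1 to 9600), and the beta-glucan recognition gene B-gluc1, 3.18-fold higher (2.70 to 3.78). The C-type lectin CTL5 had a log2 fold of -0.16, which was above 0 under plain totals and TPM. Of the antimicrobial peptide genes, Apid1 (apidaecin) stood at 101.5 against 50.2 CPM (log2 fold 1.02) and Def1 (defensin) at 126 counts against 2 (ratio 51.7, interval 14.0 to 432), while Def2 had 5 adult counts and 0 larval counts. Def1, at 6.61 CPM in the adult library, lay below the 10 CPM of the size rule.

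In the melanization list, 2 of 4 measured members were higher in the adult library beyond counting error and 1 in the larval library, with a median of 0.73 (percentile 72.44). The median was 0.07 without a count filter (percentile 56.93) and 0.10 with at least 100 counts per gene (percentile 48.15). TyHyd, tyrosine hydroxylase, had 215 adult counts and 0 larval counts. At the floor of 3 counts it was at least 58.8-fold higher in the adult library (exact interval from 47.45). Y-y, a yellow family gene, had a log2 fold of 0.07. PPO was its larval-side member and the single measured hemocyte marker. Of the toll and Imd pathway genes (3 measured, median 0.18, percentile 65.96), the toll family receptor 18-w was 3.06-fold higher in the adult library (log2 fold 1.62). Imd stood at 0.18 and cact1, the inhibitor cactus, at -0.34, the latter above 0 under plain totals and TPM.

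Few surface genes carried a symbol. The immunoglobulin receptor Dscam had a log2 fold of -0.34 (above 0 under plain totals and TPM) and the tetraspanin Tspan6, at 311.5 and 417 CPM, -0.42 (above 0 under TPM). The cell adhesion list had a median of 0.29 over 5 measured genes (percentile 47.46), with 3 higher in the adult library beyond counting error and 1 in the larval library, and a median of 1.20 without a count filter (percentile 93.98). Its widest difference was NLG-4, a neuroligin, 14.5-fold higher in the adult library (10.3 to 21.7), while NLG-3 had a log2 fold of 0.23 and uzip, the most abundant, 0.29. The lysosomal proton pump subunit Vha16 had a log2 fold of 0.34.

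The storage proteins formed the list farthest to the larval side, with a median log2 fold of -6.02 over 7 genes (percentile 0) and 6 of 7 higher in the larval library. Vg was the exception. The transferrin gene Tsf1 was 2.28-fold higher in the larval library. These 7 fat body genes held 0.0214% of adult counts (0.0207 to 0.0221) and 0.610% of larval counts (0.607 to 0.614). All 146 genes of the other-tissue lists held 0.248% and 0.694%. These lists hold only genes that could be assigned by symbol, so the values do not measure the whole share of other tissues. The neuronal list alone held 0.167% of adult and 0.0414% of larval counts, with Syt1 its most abundant member. Whether hemocytes themselves express genes of these lists was not tested. The silk gland list, genes of cocoon silk, was also on the larval side (4 genes, median -2.14, percentile 0.59), and Fibroin2 was 6.26-fold higher there (5.05 to 7.90), at 32.0 against 5.09 CPM.

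Mitochondrially encoded genes were higher in the larval library for 12 of 13 members, with a median of -1.89 (percentile 0). They held 1.92% of adult counts (1.918 to 1.931) and 5.44% of larval counts (5.433 to 5.454). The exception, ATP8, had 7 adult and 5 larval counts. The 8 nuclear-encoded genes of oxidative phosphorylation had a median of -0.22 (percentile 46.87), which was above 0 under plain totals and TPM, and ATP5G2 was their most larval member (log2 fold -1.41).

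The ecdysone and juvenile hormone list, which governs moulting and metamorphosis, lay on the larval side (12 genes, 7 higher in the larval library beyond counting error and 2 in the adult library, median -0.71, percentile 1.12). Besides Br-c and E74, Usp, a subunit of the ecdysone receptor, was 3.46-fold higher in the larval library (3.18 to 3.77). Ecr, the other subunit, had a log2 fold of -0.20, but its TPM was higher in the adult library (27.4 against 20.3). Mblk-1 was the member farthest to the adult side. With at least 100 counts per gene the median of the list was -0.11 (percentile 26.59).

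Antioxidant genes had a median of -1.05 (percentile 1.54), with 7 of 10 higher in the larval library. Cat, catalase, was 3.82-fold higher there (3.62 to 4.03), and Sod1, a superoxide dismutase, 3.08-fold. Trxr-1, thioredoxin reductase, had a log2 fold of -0.66. Tpx-4 was 3.47-fold and Gtpx1 2.14-fold higher in the adult library. From the single coding sequence with the most counts the median was -0.81 (percentile 8.34), and the mean of members was -0.54 (percentile 18.38).

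Other cell processes did not lie apart from matched lists. Ribosomal protein genes were higher in the larval library for 6 of 7 members (median -1.22, percentile 10.67, random median -0.51). The glycolysis and citric acid cycle list had a median of -0.72 (3 of 3 higher in the larval library, percentile 14.45). Its members by symbol were Tpi at -1.35, PDHB at -0.72 and Gpdh at -0.67. The planned pattern did not name PDHB, a pyruvate dehydrogenase subunit that set the median, so these genes do not stand for the pathways as a whole. Chaperones had a median of -0.79 (percentile 34.80), with Hsp90 at -0.96 and Hsc70-4 at -0.21, the latter above 0 under plain totals and TPM.

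The lists added once the gene table was seen went apart. The 3 measured CYP6 genes, cytochrome P450s of detoxification, were all higher in the adult library (median 2.47, percentile 98.13). Only 4 of 34 odorant receptor genes were measured, with a median of -2.72 (percentile 0.26). Or13 had 55 larval counts and 0 adult counts, at least 22.3-fold higher in the larval library at the floor of 3 counts (exact interval from 17.6). Its 3.52 CPM in the larval library lay below the 10 CPM of the size rule. Without a count filter the odorant receptor median was -0.29 (percentile 48.8).

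Among markers of other tissues, the cuticle list was split, with 6 of 20 measured members higher beyond counting error in each library (median -0.10, percentile 9.67). The median was above 0 under plain totals, under TPM and with at least 100 counts per gene, and so was the mean of members. Its apidermin gene Apd-2 had 381 adult counts and 0 larval counts, at least 104-fold higher in the adult library, and CPF2 had a log2 fold of -0.32 (above 0 under plain totals and TPM). Of 18 neuronal genes, 9 were higher in the adult library beyond counting error and 2 in the larval library (median 0.72, percentile 89.06), led in abundance by Syt1, synaptotagmin 1, at 1094 against 244 CPM (4.48-fold, 4.33 to 4.64). Odorant-binding and chemosensory genes had a median of 0.78 (14 measured, percentile 81.46, and -0.29 without a count filter), with Obp10 at 1.16 and Obp3 at 310 adult counts against 2 (ratio 127, interval 34.9 to 1056).

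The royal jelly list had a median of 0.88 (7 measured, percentile 87.66), or 0.03 without a count filter (percentile 49.36), with Mrjp7, a major royal jelly protein, 42.9-fold higher in the adult library (25.9 to 84.1) and the alpha-glucosidase Hbg3 2.45-fold higher in the larval one. Muscle genes, troponins in this list, had a median of -0.38 (7 measured, percentile 11.71), with TpnCI at -0.38 and TpnT at -0.86. The muscle median and TpnCI were above 0 under TPM and when the single coding sequence with the most counts stood for each gene. Venom gland genes had a median of -0.50 (3 measured, percentile 20.39, above 0 under TPM and as a mean of members), with C1q-VP at 1.69. Of the oenocyte genes, Cyp4g11 is given above and FAR1 had a log2 fold of -0.68.

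**Figure D2:**
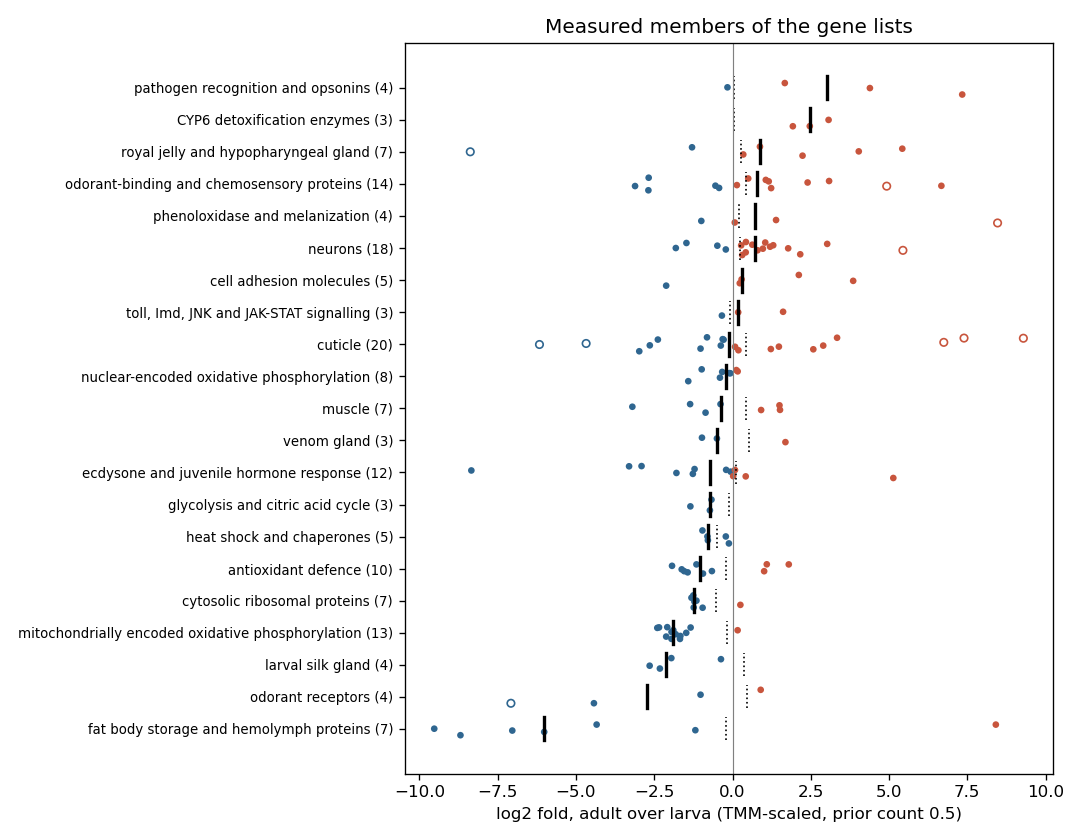
Log2 fold, adult over larva, of each measured member of the 21 gene lists with at least 3 measured members (points, red above 0 and blue below 0, open where 1 library had 0 counts), with the list median (thick bar) and the median of matched random lists (dotted bar). Storage proteins (median -6.02) and mitochondrially encoded genes (-1.89) lie to the larval side and pathogen recognition (3.03) to the adult side, and 4 medians near 0 (cuticle, nuclear-encoded oxidative phosphorylation, muscle and venom gland) lie above 0 under the authors' TPM.

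Of the 21 lists, 2 lay apart on the adult side, 6 on the larval side and 13 on neither. The random lists were drawn from all compared genes, most of which have a locus number only, while nearly all list members have a symbol. The 315 compared genes with a symbol had a median log2 fold of -0.21, and 21 met the size rule on each side. How far this class difference moved lists apart was not tested. Without a count filter, 3 lay apart on the adult side and 5 on the larval side among 22 lists. Genes with longer coding sequences were relatively higher in the adult library: the median log2 fold was -0.10 in the shortest eighth of genes and 0.36 in the longest. With random lists matched on coding length as well, a choice made after seeing the data, no list changed side, and placing genes with 0 counts at their bound moved none of the 21 medians. The median log2 fold was 0.50 in the eighth with the lowest mean CPM and -0.43 in the eighth with the highest. The median over all 8798 genes was 0.02 with TMM scaling, 0.37 with plain totals and 0.55 with the authors' TPM, and log2 folds are given relative to the TMM scale. Of the genes that met the size rule, 53.6% were higher in the adult library, against 72.1% with plain totals (413 against 160 genes) and 79.7% with TPM (556 against 142 genes).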

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

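The size thresholds, scalings, count filters, priors and totals were chosen before the data were examined, while random lists matched on coding length, members matched by the first patterns alone and totals without the mitochondrial genes were chosen after seeing the data. The 17 alternatives gave 557 values of the 62 named genes (at most 9 per gene) and 253 list values (at most 13 per list). Of these, 129 gene values left their counting interval and 38 list values moved. No value changed sign for a gene that met the size rule or a list that lay apart, the values called here. For genes this was largely set in advance, since a 4-fold difference is wider than the shifts between the scalings. Among values too small to be called, 9 named genes and 5 lists changed sign under at least 1 alternative. The adult and larval gene counts became 556 and 142 with the authors' TPM, which apply no TMM factor and no interval, 879 and 931 at 2-fold, and 120 and 86 at 8-fold, both of these by construction. They were 413 and 160 with plain totals and stayed within 1.5 times the reported counts under the other alternatives. With at least 100 counts per gene, 1 list on the adult and 3 on the larval side lay apart among 17 lists, since the silk, CYP6 and odorant receptor lists kept under 3 measured members and the ecdysone list came to percentile 26.59. With members matched by the first patterns alone, 6 lists could be placed, of which 4 lay apart on the larval side (storage proteins, silk, ecdysone and mitochondrial genes) and 1 on the adult side, the royal jelly list at percentile 98.34. Without a count filter the counts were 3 and 5 among 22 lists, as the antimicrobial peptides gained a measured member and a place on the adult side and the odorant receptors lost theirs on the larval side. The melanization list came to percentile 97.88 with the mean of members, which TyHyd raised. Its log2 fold was 8.47, a value set by the prior at 0 larval counts, while the other measured members ran from -0.997 to 1.39. By TPM, the 10 most abundant genes held 9.98% in the adult and 11.4% in the larval library, since TPM divide by length. No paired analysis was possible because each stage has 1 library and the labels carry no replicate numbers, and for the same reason no library could be left out. Depth limits genes below 0.158 CPM in the adult and 0.192 CPM in the larval library. Thinned to the smaller total, the larval library still showed 9228 genes.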

Other observations

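The tests on storage proteins, on mitochondrial genes and on the upper 4 of 5 bins of mean CPM were chosen only after the results were seen, as were the further genes and neighbour counts named here. Among the 315 compared genes with a symbol, 21 met the size rule on each side, against 276 (adult) and 239 (larva) of all 8798. The octopamine receptor gene Oa1 was 28.3-fold higher in the larval library (18.2 to 49.6), at 27.5 against 0.945 CPM. The chloride channel gene pHCl was 6.53-fold higher there and EphR, an ephrin receptor, 5.94-fold. The fatty acid-binding protein gene Fabp_409798 was 7.25-fold higher in the larval library, and the odorant-binding gene Obp1 6.44-fold higher, with Obp13 at 22.3 against 3.46 CPM. On the adult side, the circadian clock gene Per was 37.5-fold higher (20.0 to 92.9), at 20.4 against 0.511 CPM. Mrjp8 was 16.4-fold higher in the adult library and the chemosensory protein gene CSP3 5.27-fold.

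Genes of one family went both ways. Among chitin-binding cuticle genes, Cpap3-d was 7.45-fold higher in the adult library while Cpap3-b was 6.24-fold higher in the larval one. Mrjp7 and Mrjp8 were on the adult side, and Mrjp3 had 136 larval counts against 0 adult counts. At the floor of 3 counts Mrjp3 was at least 55.2-fold higher in the larval library (exact interval from 44.3). At 8.69 CPM there it lay below the 10 CPM of the size rule. Among adhesion genes, Nrx-1 (neurexin) was 4.34-fold higher in the larval library, with an interval (3.29 to 5.87) that fell short of the size rule. Of the genes that met the size rule, 46 pairs of neighbours on a chromosome lay on the same side, against a median of 15 and a highest value of 27 in 1000 shuffles. The storage protein genes Hex70a, HEX70b and Hex70c are such neighbours. The shuffles make no allowance for near-identical neighbouring copies, among which kallisto divides reads, or for overlapping antisense genes. The cause of the excess was not tested.

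The first pattern is that hexamerins were abundant in the larval library and low in the adult one. Carry-over of larval reads bears only on the adult counts and would weaken this pattern, not produce it. At a constant rate it would leave equal percentages of the larval counts, but these ran from 0.163% for HEX70b (0.122 to 0.214) to 5.998% for Hex70a (5.24 to 6.84). Carry-over may still account for the adult counts of HEX70b. A larger share of the same fat body cells in the larval pellet would move all fat body genes to the larval side, whereas Vg had a log2 fold of 8.4114 and HEX70b one of -9.53. Fat body cells of each stage in the pellets cannot be told apart from expression in hemocytes, since 0 fat body libraries were at hand to give the ratio of their transcripts, and the difference in stage itself stays open.

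The next pattern is the higher level of mitochondrially encoded transcripts in the larval library. A scaling factor moves all genes by the same amount, so it can neither make nor remove a distance from the median of all genes. The mitochondrial median lay -1.9124 from it, a value that restates the pattern and is no separate test. The median of nuclear-encoded oxidative phosphorylation genes was -0.22. COX1 did not carry the pattern alone, as the other 12 genes had a median of -1.9201. This could be foreseen, since 12 of the 13 genes were already known to be higher in the larval library. A difference in RNA quality or poly(A) selection between the preparations cannot be told apart from stage with 1 library per stage. A stage difference in hemocytes stays open and untested.

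The last pattern is that the log2 fold was larger for genes with longer coding sequences, with a gap of 0.46 (0.35 to 0.57) between the longest and shortest eighths. Intervals of these gaps are bootstrap intervals over genes and show the spread among genes within these 2 libraries, not between bees or preparations. Fragment size does not account for it as a whole, since the gap in the authors' TPM, which divide by effective length, was 0.5413 (0.443 to 0.645). The trend with mean expression was tested within 5 equal bins of mean CPM. Each bin was compared between its 440 longest and 440 shortest genes, against 1100 per end over all genes. From the lowest bin up, the gaps were -0.0452 (-0.33 to 0.15), 0.3774 (0.248 to 0.545), 0.4133, 0.5254 and 1.054 (0.913 to 1.169). The gaps in the upper 4 bins argue against the trend with mean expression as the whole account there. The gap still rose with mean expression, and the cause of this rise was not tested. For genes of low expression the question is open. Among genes with 1 coding sequence the gap was 0.19 (0.04 to 0.33). A difference in RNA integrity between the preparations may be the source and cannot be told apart from stage with 1 library per stage.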
